A study of Homo sapiens with 33 samples.

How the data were processed

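The data are 33 Illumina bead arrays of total RNA from human H9 embryonic stem cells, in 11 groups of treatment and day with 3 arrays each. Groups were taken from the sample labels alone. The submitters name GenomeStudio in their processing notes, and its version is not given in the sources used here. The deposited non-normalized table holds, for each array, a bead summary intensity per probe on a linear scale, and a detection p-value per probe (unit p_value) against negative controls. The authors' processed table holds intensity values on a linear scale that share nearly the same distribution across arrays (medians from 172.4 to 172.7), so it was treated as quantile-normalized and not background-subtracted.

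The probe IDs of the authors' processed table were checked against the non-normalized table. Joined by ID, the log2 values of an array correlated at 0.227 to 0.290 over probes. Matched one to one by their ranks over the 33 arrays, 48780 of 48803 probes found a partner with a largest distance of 0.000914, against at least 0.00238 to the next nearest, and 23 had no value. The correlation was then at least 0.983. Of the matched pairs, 2395 (4.91%) carry the same ID. Pairs of probes for 1 gene had a median correlation across arrays of 0.224 under the IDs of the processed table (1657 pairs) and 0.582 under the matched IDs (1792 pairs). A GAPDH probe averaged 24799.6 in the non-normalized table and 733.6 under the same ID in the processed table. The non-normalized table was therefore the main source, and the processed values entered as an alternative under the matched IDs.

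Intensities were corrected with the normexp method of limma 3.58.1 in R 4.3.3, with the background inferred from detection p-values and an offset of 16, then quantile-normalized and taken to log2. A probe entered if its detection p was under 0.01 on all 3 arrays of at least 1 group (14651 probes, 12708 of them with 1 gene symbol). The probe with the highest mean stood for each gene, which left 10038 genes. One linear model with 11 group means (22 residual degrees of freedom) was fitted with lmFit and eBayes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 change of at least 1. The 9 comparisons were LSB3i against LSB at days 3, 5, 7, 9 and 15, LSB day 15 against days 2 and 3, LSB3i day 15 against day 3, and the difference between the last 2 changes from day 3. No LSB3i array of day 2 was analysed here.

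Gene lists, 22 in number, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, with camera at an estimated correlation and fry beside it. They cover pluripotency, anterior neuroectoderm, neural crest, sensory and pan-neuronal genes, Notch, Wnt, FGF and BMP targets, proneural genes, cell cycle, HOX genes, other cell types, stress, cholesterol synthesis and hypoxia. The comparisons, thresholds, lists, alternatives and the rule for naming genes were chosen before the data were examined. That rule allows the 8 highest and 8 lowest called genes with non-overlapping groups per comparison, up to 4 called members at each end of a list (or the 2 most shifted of a list with none called), and a fixed panel. It allows 925 gene values. The text prints a part of them, and genes whose call held under the alternatives were preferred for printing, a choice made after the alternatives had been run, so the printed genes are steadier than the whole set.

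Where a gene was above background on no array of 1 group, the fold is given as a lower bound against the lowest detected intensity of each array, or only the p where no bound could be set, where both groups were at background, or for a difference of changes. Mean signals ranged from 298 to 872 per array, and the median standard error was 0.281 for a difference of 2 groups and 0.397 for the difference of changes. On simulated data, 100 genes raised or lowered by 1.5 on the log2 scale were recovered in 55 to 89% of cases over the 9 comparisons, and by 2.5 in 91 to 99%. At most 7 of 9838 unchanged genes were called, and 0 of 20 unchanged lists passed. The simulated genes were drawn independently, each with 1 spread for all arrays. The real groups differed in pooled residual SD, from 0.213 (LSB day 5) to 0.813 (LSB day 7). Of 77 list results past the threshold, 30 were lost with an estimated correlation. The simulated rates therefore do not give the rates of recovery or of false calls in the real arrays, for genes or for lists. Deviations from group means correlated at 0.00384 on average for the same letter and -0.00152 for different letters. In 2 of 55 pairs of groups, LSB3i days 5 and 7 and LSB3i days 7 and 9, all 3 same-letter correlations were over 0.1 (lowest 0.121 and 0.150). The labels do not say that letters mark a shared culture, so no block was fitted in the main model.

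Alternatives changed 1 choice at a time with 2 exceptions. The first listed here changed the offset and the use of detection p-values together, and the authors' processed values (10030 genes tested) replaced the background correction, its offset and the normalization at once. The alternatives were: the background (normexp with an offset of 50 and no detection information), median scaling, the authors' processed values, no detection filter, detection on at least 17 arrays, a detection threshold of 0.05, the mean of all probes of a gene, only the groups compared, the letter as a block, an intensity trend, array weights (statmod 1.5.0), the fold minimum, and leaving out each array. Leaving out the LSB3i A arrays of days 3 to 9, alone or with array C of LSB days 2 and 7, was chosen after seeing the data. A block for the BeadChip was not run, since the files used here do not give the chip. Random draws used seed 1.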

Results

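Gene expression was measured over a time course in which human embryonic stem cells were differentiated with 2 sets of small-molecule inhibitors. The cells were of the established line H9 (WA-09), kept on mouse feeder cells and plated on Matrigel for differentiation. LSB cells received LDN-193189, an inhibitor of BMP type I receptors, and SB431542, an inhibitor of the TGF-beta, activin and nodal receptors. LSB3i cells received the same pair plus CHIR, an inhibitor of the kinase GSK3 that activates Wnt/beta-catenin signalling, DAPT, an inhibitor of gamma-secretase and so of Notch signalling, and SU5402, an inhibitor of FGF and VEGF receptors. The labels name the first treatment a neural and the second a nociceptor differentiation. They do not say on which day each inhibitor was added or withdrawn. Total RNA was hybridized to Illumina bead arrays, 3 per group, on days 3, 5, 7, 9 and 15 of both treatments and on day 2 of LSB, which makes 33 arrays in 11 groups. LSB3i at day 2, which the series design lists, was not analysed here.

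The mean signal of an array ranged from 298 to 872, and between 9320 and 13743 of 48803 probes were detected per array. The dimmest array was C of LSB day 7, and the mean signals of the day 15 arrays lay between 427 and 513. The number of arrays limits the precision. The median standard error of a log2 difference between 2 groups was 0.281. The labels do not say whether the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays. Along the first principal component, which held 34.4% of the variance, LSB3i day 15 stood far from all others. Of the 33 arrays, 9 correlated best with a group other than their own. Among them, the LSB3i arrays lettered A of days 5, 7 and 9 had mean correlations of 0.989, 0.989 and 0.986 with the B and C arrays of the day before, against 0.959, 0.958 and 0.970 with B and C of their own day. Of the others, the arrays labelled LSB3i day 3 A and B correlated best with LSB day 3, LSB day 7 A and B with LSB day 5, and LSB3i day 7 B and C with LSB3i day 9. These ranks use group means that include arrays standing apart. Array A of LSB3i day 3 had a mean correlation of 0.961 with its own group and 0.974 with LSB day 3. For array B of LSB3i day 3 the values were 0.976 and 0.978. With each other, LSB3i day 7 B and C correlated at 0.992 and LSB3i day 3 B and C at 0.990. These values lie above the means of LSB3i day 7 B and C and LSB3i day 3 B with those other groups (0.977 to 0.978). All arrays keep their labelled groups below, and counts without the LSB3i A arrays of days 3 to 9 are given where they differ by more than 1.5 times.

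**Figure D1:**
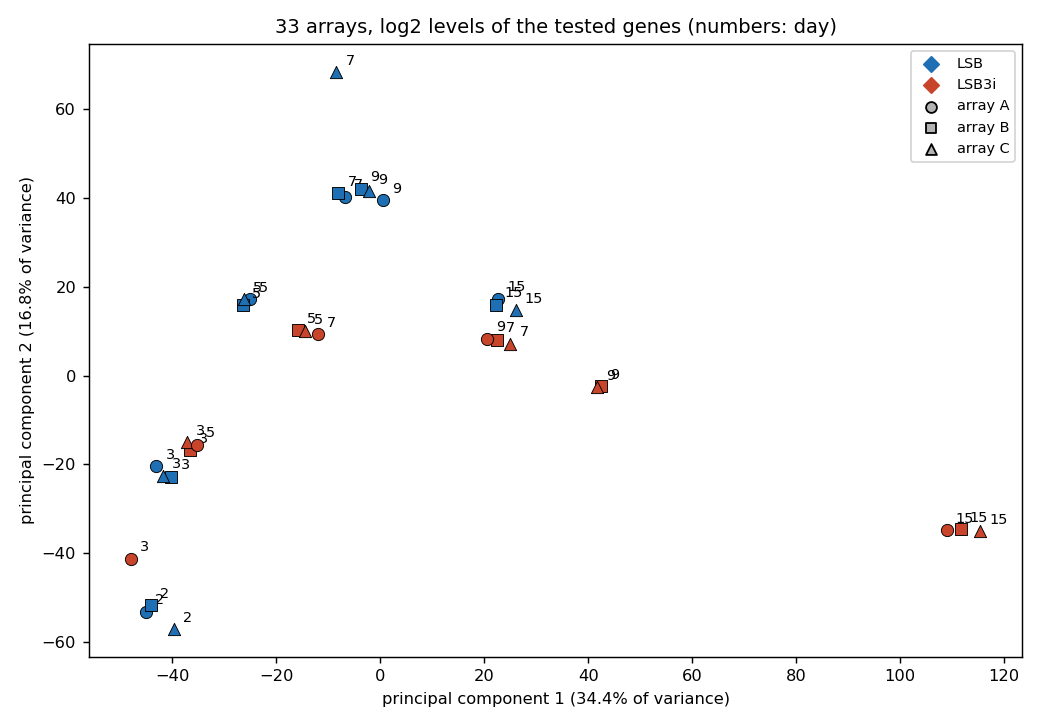
First against second principal component of the log2 intensities of the tested genes, 1 point per array; the number is the day, the colour the treatment and the shape the array letter. The components hold 34.4% and 16.8% of the variance, and the LSB3i A arrays of days 5, 7 and 9 sit beside the B and C arrays of the day before.

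The first comparison asks how LSB3i differed from LSB at day 3, the earliest day measured under both treatments. SIX3, FEZF1 and RAX, which encode transcription factors of the forebrain and eye field, were lower in LSB3i. SIX3 was at least 4.35-fold lower (adjusted p = 1.8e-06), FEZF1 differed by -2.25 ± 0.34 (log2 ± SE, 3 arrays per group) and RAX, at background in LSB3i, was lower (adjusted p = 9.3e-05). The metallothionein genes MT2A (-1.91 ± 0.22) and MT1X (adjusted p = 8.7e-05), whose proteins bind zinc and copper, were also lower. The 5 genes that were higher were WNT4, a secreted Wnt ligand (at least 2.19-fold), the immediate-early gene FOS (1.94 ± 0.38), the small GTPase gene RHOB (1.66 ± 0.35), IGFBP5 (1.39 ± 0.27) and TRIB2 (1.11 ± 0.23). Fold values given as "at least" concern genes above background in 1 of the 2 groups, and set the other at the lowest detected intensity of each array.

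Of 24 anterior neuroectoderm and neural progenitor genes tested at day 3, 3 were lower and 0 higher (1 higher and 5 lower adjusted over the list alone, adjusted p = 1.3e-05). The median of the list was -0.27 as fitted and 0.09 with values at background set to the floor. The cholesterol synthesis list was shifted upward without a called member among 13 (adjusted p = 1.3e-05, with 0 higher and 0 lower adjusted over the list alone). Its most shifted genes were IDI1 (0.66 ± 0.24) and HMGCS1 (0.53 ± 0.20), which encode enzymes of the mevalonate pathway. FGF/ERK targets lay lower as a list (adjusted p = 0.00685), although the 1 called gene of 17, FOS, was higher (2 higher and 3 lower adjusted over the list alone). That list test gave adjusted p = 0.245 with an estimated correlation, and adjusted p = 0.126 with only the day 3 groups fitted. Relative to LSB day 2, the mean log2 change of these targets was 0.07 on array A of LSB3i and -0.79 and -0.82 on arrays B and C. AXIN2, a feedback target of beta-catenin, stood at 1.40 ± 0.37 (adjusted p = 0.197), and the Wnt/beta-catenin target list did not pass its test (adjusted p = 0.126).

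In all, 26 of 10038 genes differed at day 3 at an adjusted p under 0.05 and at least 2-fold, 5 higher and 21 lower in LSB3i, and in all 26 the 3 arrays of one group lay above the 3 of the other. Chance gives that in 10% of genes, but calls made on the same arrays select for it, here and below. The count was 90 without array A of LSB3i day 3, 11 without its array C and 142 without the LSB3i A arrays, where Wnt targets were higher (adjusted p = 2.3e-05, up to 0.447 in other alternatives) and pluripotency genes lower (adjusted p = 2.3e-05, up to 0.634). FOS, RHOB, IGFBP5 and TRIB2 each lost the call when array B or C of LSB3i day 3, or at least 1 LSB day 3 array, was left out, at adjusted p values from 0.0645 to 0.306. RAX fell short of 2-fold in the authors' processed values (-0.76), and WNT4 lost the call with only the day 3 groups fitted (adjusted p = 0.0749, the highest of its alternatives). IGFBP5, RHOB and TRIB2 lost it there too (adjusted p = 0.126, 0.126 and 0.267).

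Day 5 asks the same question 2 days later. LHX2 and RAX, transcription factors of the eye field, were at least 30.4-fold and at least 16.7-fold lower in LSB3i (adjusted p = 2.5e-12 and 1.7e-16). HES5, an effector of Notch signalling, was at least 17.9-fold lower, and HES1 (-2.86 ± 0.34), HES4 (-1.96 ± 0.28) and LFNG (-1.80 ± 0.25), a glycosyltransferase that modifies Notch, were lower with it. SPRY1 (-3.25 ± 0.37) and SPRY2 (-2.73 ± 0.51), feedback inhibitors of FGF receptor signalling, were lower, as was the glucose transporter gene SLC2A1 (-2.34 ± 0.27). AXIN2 (2.20 ± 0.37), the Wnt antagonist gene DKK1 (3.21 ± 0.59), MSX1, a homeobox gene of the neural plate border (at least 5.87-fold), and POU4F1, a transcription factor of sensory neurons (at least 5.37-fold), were higher.

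The anterior neuroectoderm list held 1 higher and 8 lower genes of 24 (2 higher and 11 lower adjusted over the list alone, adjusted p = 1.1e-15), with HESX1 (-4.82 ± 0.62), a forebrain homeobox gene outside the list, among the genes with the largest decreases. Notch pathway targets were lower (6 of 11, with 0 higher and 6 lower adjusted over the list alone, adjusted p = 6.2e-10), as were FGF/ERK targets (6 of 17, with 0 higher and 7 lower adjusted over the list alone, adjusted p = 1.5e-06) and hypoxia and glycolysis genes (7 of 17, with 0 higher and 10 lower adjusted over the list alone, adjusted p = 8.1e-11). Wnt/beta-catenin targets were higher (7 higher and 1 lower of 15, with 7 higher and 1 lower adjusted over the list alone, adjusted p = 2.8e-05), among them APCDD1 (at least 4.77-fold) and TNFRSF19 (3.08 ± 0.59). Stress genes were higher (4 of 13, with 4 higher and 0 lower adjusted over the list alone, adjusted p = 2.1e-04), including ATF3 (2.15 ± 0.36), a transcription factor induced by stress, and ASNS, asparagine synthetase (1.30 ± 0.29). Their list test gave adjusted p = 0.0541 with an estimated correlation. The median of the stress list was 0.60 as fitted and 0.11 with values at background set to the floor. Neural crest genes were higher as a list (3 of 19, with 4 higher and 1 lower adjusted over the list alone, adjusted p = 0.0292), with ETS1 at least 4.08-fold higher. The neural crest list gave adjusted p = 0.514 with an estimated correlation, 0.0515 with median scaling, 0.291 with probes on at least 17 arrays, 0.0526 with the mean of all probes and 0.138 with only the day 5 groups. Its median was 0.17 as fitted and -0.04 with values at background set to the floor. Relative to LSB day 2, their mean log2 change was 0.05 on array A of LSB3i and 1.15 and 1.39 on arrays B and C.

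At day 5, 323 genes differed, 110 higher and 213 lower, with non-overlapping groups in 319 of them (10% by chance). The count was 494 without the LSB3i A arrays, 200 without array A of LSB day 5 and 170 from the authors' processed values. POU4F1 lost the call when only the day 5 groups were fitted (adjusted p = 0.0611, the highest of its alternatives).

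At day 7, MSX1 (5.59 ± 0.66), POU4F1 (at least 7.37-fold), WNT1, a ligand of the dorsal midline (at least 7.06-fold), LMX1A, a roof plate transcription factor (at least 9.45-fold), and TFAP2B, a neural crest transcription factor (at least 4.16-fold), were among the genes higher in LSB3i by the largest margins. HES5 was at least 81.7-fold lower (adjusted p = 2.6e-12), and LHX2 (-6.50 ± 0.37), SPRY1 (-5.59 ± 0.37), HES4 (-4.37 ± 0.28) and LFNG (-3.47 ± 0.25) were lower. AXIN2 differed by 3.04 ± 0.37 and APCDD1 by 5.10 ± 0.61. GAP43, a protein of growing axons, was higher by 3.27 ± 0.41.

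Neural crest genes were higher (11 of 19, with 11 higher and 0 lower adjusted over the list alone, adjusted p = 1.4e-05). The neural crest list gave adjusted p = 0.124 with an estimated correlation. Pan-neuronal genes split into 16 higher and 3 lower of 38 (18 higher and 4 lower adjusted over the list alone, adjusted p = 0.00216). The pan-neuronal list gave adjusted p = 0.325 with an estimated correlation, 0.354 with median scaling and 0.38 with probes on at least 17 arrays. Its median was 0.84 as fitted and -0.06 with values at background set to the floor, and the floors of the LSB day 7 arrays were high. The sensory neuron and nociceptor list had 4 higher and 1 lower of 16 (4 higher and 1 lower adjusted over the list alone) and did not pass (adjusted p = 0.184). It passed without the LSB3i A arrays (adjusted p = 0.00497, up to 0.992 in other alternatives). With all arrays its median was 0.71 as fitted and -0.78 with values at background set to the floor, so its direction depends on values at background. On array A of LSB3i day 7 the pan-neuronal genes stood 0.18 above LSB day 2 on the log2 scale, against 1.19 and 1.43 on arrays B and C. Anterior neuroectoderm genes (13 of 24 lower, 1 higher, with 1 higher and 13 lower adjusted over the list alone, adjusted p = 2.6e-08) and Notch targets (5 of 11 lower, 1 higher, with 1 higher and 5 lower adjusted over the list alone, adjusted p = 5.4e-05) stayed lower, and Wnt targets higher (9 of 15, with 9 higher and 0 lower adjusted over the list alone, adjusted p = 6.8e-04). FGF/ERK targets were lower as a list (2 higher and 3 lower of 17, with 2 higher and 3 lower adjusted over the list alone, adjusted p = 0.0445), with adjusted p = 0.267 with an estimated correlation, 0.143 without the LSB3i A arrays, 0.0851 with probes on at least 17 arrays and 0.101 with array weights. The mesenchyme and smooth muscle list was higher (5 of 12, with 5 higher and 0 lower adjusted over the list alone, adjusted p = 0.0445), with TAGLN, an actin-binding protein of smooth muscle, at 1.99 ± 0.40. The mesenchyme list gave adjusted p = 0.267 with an estimated correlation, 0.329 with median scaling, 0.0585 with probes on at least 17 arrays and 0.085 with the mean of all probes, and its median was 0.89 as fitted and -0.08 with values at background set to the floor. Stress (5 higher and 0 lower of 13, with 6 higher and 0 lower adjusted over the list alone, adjusted p = 0.00753) and cholesterol synthesis genes (3 higher and 0 lower of 13, with 3 higher and 0 lower adjusted over the list alone, adjusted p = 0.0108) were higher. Hypoxia and glycolysis genes were lower (2 higher and 7 lower of 17, with 2 higher and 7 lower adjusted over the list alone, adjusted p = 0.00623). With an estimated correlation these 3 lists gave adjusted p = 0.177, 0.124 and 0.124. The median of the stress list was 0.88 as fitted and 0.28 with values at background set to the floor.

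Of the 1938 genes that differed at day 7, 1285 were higher and 653 lower in LSB3i, and 1627 had non-overlapping groups (10% by chance). With the arrays scaled to a common median the split was 617 higher and 1339 lower, and the median of all genes moved from 0.086 to -0.132. The count was 714 when only the day 7 groups were fitted, 798 from the authors' processed values and 1182 with a background correction that used an offset of 50 and no detection p-values. The main fit shares 1 spread per gene over all 11 groups. The residual SD of LSB day 7 was 0.813, against at most 0.457 in the other groups. The day 7 p-values of the main fit thus rest on a spread smaller than that of LSB day 7. Fitting only the day 7 groups also leaves fewer arrays to estimate the spread.

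At day 9, the genes higher in LSB3i included genes of sensory neurons and of neurons in general. POU4F1 was at least 32.3-fold higher (adjusted p = 4.3e-08), SST, the neuropeptide somatostatin, at least 32.1-fold, and ISL1, a LIM homeobox factor of sensory and motor neurons, at least 21.7-fold. The synaptic vesicle gene SYT4 (at least 36.4-fold), DCX, a microtubule-associated protein of young neurons (4.15 ± 0.48), TUBB3, neuronal beta-tubulin (3.47 ± 0.38), and NEFM, a neurofilament subunit (at least 8.59-fold), were higher with them. SOX10 (at least 12.8-fold), TFAP2B (at least 27.5-fold) and ETS1 (5.01 ± 0.51), transcription factors of the neural crest, were also higher. SOX21 (-6.66 ± 0.63), LHX2 (-5.87 ± 0.37), SP8 (-5.23 ± 0.61), PAX6 (-2.59 ± 0.61) and OTX2 (-1.31 ± 0.30), transcription factors of neural progenitors, were lower.

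Among pan-neuronal genes 26 higher and 2 lower of 38 passed (27 higher and 2 lower adjusted over the list alone, adjusted p = 1.2e-14), and among neural crest genes 15 higher and 0 lower of 19 (15 higher and 1 lower adjusted over the list alone, adjusted p = 1.5e-08). The sensory neuron and nociceptor list was higher (8 higher and 1 lower of 16, with 8 higher and 1 lower adjusted over the list alone, adjusted p = 1.6e-04). On array A of LSB3i day 9 it stood 0.86 above LSB day 2 on the log2 scale, against 2.09 and 2.19 on arrays B and C. The sensory neuron list gave adjusted p = 0.0991 with an estimated correlation and 0.653 with probes on at least 17 arrays, where the Wnt and BMP lists gave 0.0774 and 0.0769. The mesenchyme and smooth muscle list was higher beside the neural crest list (4 higher and 1 lower of 12, with 5 higher and 1 lower adjusted over the list alone, adjusted p = 0.0228), with adjusted p = 0.2 with an estimated correlation and 0.653 with probes on at least 17 arrays. SLC17A6, a vesicular glutamate transporter, was at least 2.03-fold higher. The anterior neuroectoderm list was lower (1 higher and 17 lower of 24, with 1 higher and 17 lower adjusted over the list alone, adjusted p = 2.6e-13). Notch targets had 1 higher and 8 lower of 11 (1 higher and 8 lower adjusted over the list alone, adjusted p = 8.6e-07), with HES5 at least 158-fold lower, and FGF/ERK targets had 1 higher and 9 lower of 17 (1 higher and 9 lower adjusted over the list alone, adjusted p = 4.1e-07), including ETV5 (-3.73 ± 0.37) and DUSP6 (-2.59 ± 0.38). Wnt targets had 10 higher and 1 lower of 15 (10 higher and 1 lower adjusted over the list alone, adjusted p = 0.00102). Cell cycle genes were higher as a list (4 of 29, with 4 higher and 0 lower adjusted over the list alone, adjusted p = 0.00325), led by RRM2 (2.71 ± 0.34), a subunit of ribonucleotide reductase. The cell cycle list gave adjusted p = 0.266 with an estimated correlation. Relative to LSB day 2, its mean log2 change in LSB was 0.08 at day 7, -0.82 at day 9 and -0.22 at day 15. In LSB3i it was -0.13, -0.36 and -1.48 on the same days, so the list fell in both treatments by day 9, and further in LSB. BMP and TGF-beta targets were higher (5 of 11, with 6 higher and 0 lower adjusted over the list alone, adjusted p = 0.019), with ID3 at 1.74 ± 0.26. The BMP and TGF-beta list gave adjusted p = 0.121 with an estimated correlation.

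In total 1664 genes differed at day 9, 835 higher and 829 lower, and 1625 had non-overlapping groups (10% by chance). The count was 786 from the authors' processed values and 1081 with the background correction that used an offset of 50 and no detection p-values. Of the genes higher at day 7, 390 were also higher at day 9, where 107 would be shared by independent calls, and of the genes lower at day 7, 373 were lower at day 9, against 53.9.

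**Figure D2:**
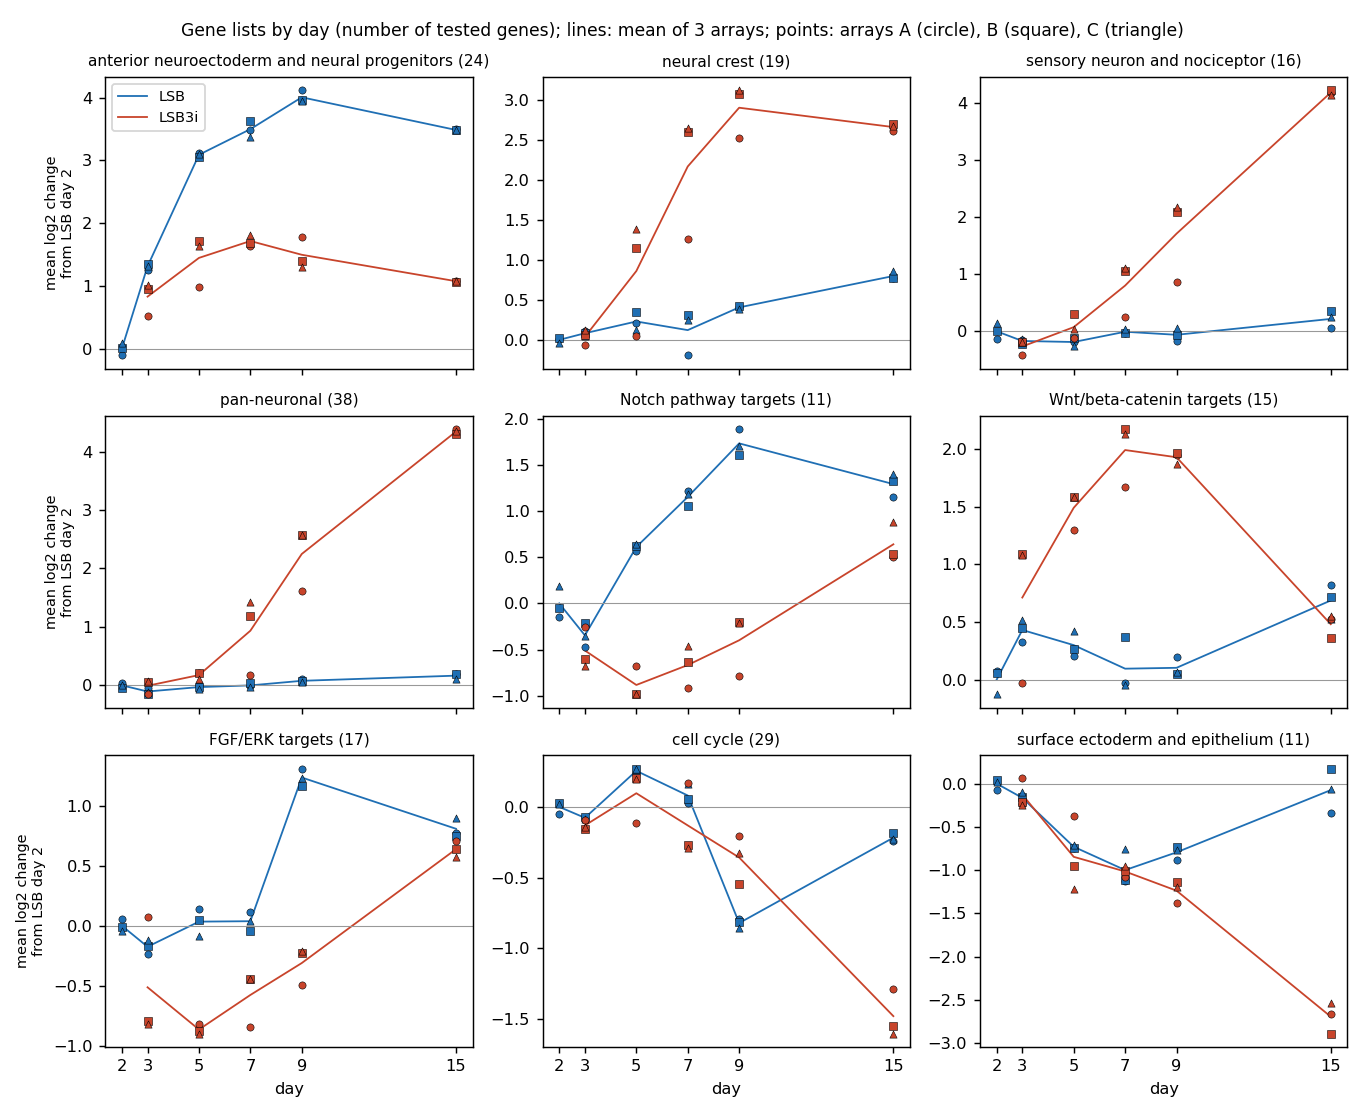
Mean log2 change from LSB day 2 of the tested genes of 9 lists (y axis) by day (x axis) for LSB and LSB3i; lines join the means of 3 arrays and points are single arrays. At day 15 the pan-neuronal and sensory neuron lists are higher in LSB3i than in LSB, and the anterior neuroectoderm list is lower.

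At day 15, the last day measured, the genes higher in LSB3i included genes of peripheral sensory, autonomic and central neurons, and the genes lower included genes of anterior neural tissue. SST was higher by 9.11 ± 0.67 (adjusted p = 2.5e-11), SYT4 by 8.38 ± 0.61 and PRPH, an intermediate filament protein of peripheral neurons, by 6.78 ± 0.35. TAC1, which encodes the substance P precursor, was at least 74.8-fold higher, and POU4F1 at least 48.2-fold. LHX2 was at least 130.4-fold lower, OTX2 differed by -7.07 ± 0.30, and SIX6 and PAX6 were at least 32.1-fold and at least 30.3-fold lower. LEFTY2, a secreted inhibitor of nodal signalling, was at least 32.2-fold lower.

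Pan-neuronal genes were higher in 35 of 38 cases and lower in 0 (35 higher and 0 lower adjusted over the list alone, adjusted p = 5.2e-26), including MAPT, the microtubule-associated protein tau (6.46 ± 0.47), NEFM (at least 44.4-fold), DCX (3.86 ± 0.48) and TUBB3 (2.52 ± 0.38). In the sensory neuron and nociceptor list 12 higher and 1 lower of 16 passed (12 higher and 1 lower adjusted over the list alone, adjusted p = 6.2e-09). ISL1 stood at 13.15 ± 0.32 (log2 intensity ± SD, n = 3) in LSB3i and 8.09 ± 0.54 in LSB, and SCN9A, a voltage-gated sodium channel of nociceptors, was at least 1.99-fold higher. The gene lower in that list was CALCB (-1.86 ± 0.31), a calcitonin gene-related peptide gene. TRPV1, the capsaicin receptor, did not pass (-0.32 ± 0.51, adjusted p = 0.645), nor did NEUROG2, at background in both groups (adjusted p = 0.512). NEUROG1 and RUNX1 did not pass the detection filter. Neural crest genes were higher (12 higher and 2 lower of 19, with 13 higher and 2 lower adjusted over the list alone, adjusted p = 1.3e-04), with SOX10 at least 19.8-fold higher and SOX9 lower (-3.23 ± 0.42). The neural crest list gave adjusted p = 0.118 with an estimated correlation. TFAP2A, a transcription factor of this list, was higher (2.85 ± 0.44), but with probes required on at least 17 arrays another probe stood for it, at -0.51 (adjusted p = 0.33).

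Lists of other cell types moved as well at day 15. Surface ectoderm and epithelium genes were lower (10 of 11, with 0 higher and 10 lower adjusted over the list alone, adjusted p = 8.5e-06), with the keratin gene KRT19 at least 19.7-fold and E-cadherin, CDH1, at least 5.23-fold lower. Cell cycle genes were lower (20 of 29, 1 higher, with 1 higher and 21 lower adjusted over the list alone, adjusted p = 6.2e-09), such as MCM2 (-2.14 ± 0.20), part of the replicative helicase, and CCNB2 (-1.87 ± 0.24), a mitotic cyclin. MKI67 was at background in both groups (adjusted p = 0.0591). Pluripotency genes were lower (11 of 16, with 0 higher and 11 lower adjusted over the list alone, adjusted p = 2.8e-05), including SALL4 (-2.89 ± 0.25) and NANOG (at least 1.9-fold). Cholesterol synthesis genes were higher (12 of 13, with 12 higher and 0 lower adjusted over the list alone, adjusted p = 1.3e-08), for example LSS, lanosterol synthase (3.20 ± 0.30), and HMGCS1 (1.98 ± 0.20). HOXA2 (at least 9.66-fold) and HOXB2 (at least 11.6-fold), homeobox genes of the hindbrain and its crest, were the 2 higher of 3 tested HOX genes (2 higher and 0 lower adjusted over the list alone, adjusted p = 7.6e-04). All 3 tested autonomic neuron genes were higher (3 higher and 0 lower adjusted over the list alone, adjusted p = 0.00433), among them the nicotinic receptor gene CHRNA3 (at least 3.79-fold). Of 5 tested central neuron genes 3 were higher (3 higher and 0 lower adjusted over the list alone, adjusted p = 0.00273), among them DLX1, a homeobox gene of forebrain interneurons (at least 18-fold). Of the listed genes, 3 of 30 HOX, 3 of 12 autonomic, 5 of 19 central and 16 of 35 sensory neuron genes were tested. A gene above background only at LSB3i day 15 entered through that group, which favours an upward shift in these lists.

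The anterior neuroectoderm list passed at day 15 (3 higher and 14 lower of 24, with 3 higher and 14 lower adjusted over the list alone, adjusted p = 2.5e-05), and the genes higher in it included MEIS2 (1.92 ± 0.54) and NES (1.62 ± 0.20). Wnt targets had 3 higher and 5 lower of 15 (3 higher and 5 lower adjusted over the list alone, adjusted p = 0.875), with AXIN2 at 0.41 ± 0.37 and DKK1 at least 12.4-fold lower. Notch targets had 2 higher and 6 lower of 11 (3 higher and 6 lower adjusted over the list alone, adjusted p = 0.104), with HES5 at -4.36 ± 0.44 and HEYL at least 11-fold higher. FGF/ERK targets (3 higher and 5 lower of 17, with 3 higher and 5 lower adjusted over the list alone), stress genes (0 higher and 5 lower of 13, with 0 higher and 5 lower adjusted over the list alone) and proneural genes and Notch ligands (2 higher and 2 lower of 8, with 2 higher and 2 lower adjusted over the list alone) gave adjusted p = 0.893, 0.152 and 0.756. Schwann cell and glia genes (3 higher and 0 lower of 5, with 3 higher and 0 lower adjusted over the list alone), melanocyte genes (0 higher and 3 lower of 3, with 0 higher and 3 lower adjusted over the list alone) and mesenchyme genes (5 higher and 2 lower of 12, with 5 higher and 2 lower adjusted over the list alone) gave adjusted p = 0.077, 0.0632 and 0.156. Mesoderm and endoderm genes (1 higher and 1 lower of 3, with 1 higher and 1 lower adjusted over the list alone) and hypoxia genes (0 higher and 2 lower of 17, with 0 higher and 2 lower adjusted over the list alone) gave adjusted p = 0.951 and 0.614. BMP and TGF-beta targets (1 higher and 6 lower of 11, with 1 higher and 6 lower adjusted over the list alone) gave adjusted p = 0.0781.

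At day 15, 2927 genes differed, 1337 higher and 1590 lower, and 2775 had non-overlapping groups (10% by chance). The count was 1662 from the authors' processed values, with which SCN9A fell short of 2-fold. With probes on at least 17 arrays the sensory neuron, HOX, autonomic and central neuron lists did not pass (adjusted p = 0.645, 0.545, 0.113 and 0.189). With no detection filter the HOX and autonomic lists did not pass either (adjusted p = 0.154 and 0.292), and their medians were 0.05 and -0.02. Autonomic genes did not pass at a detection threshold of 0.05 (adjusted p = 0.173).

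**Figure D3:**
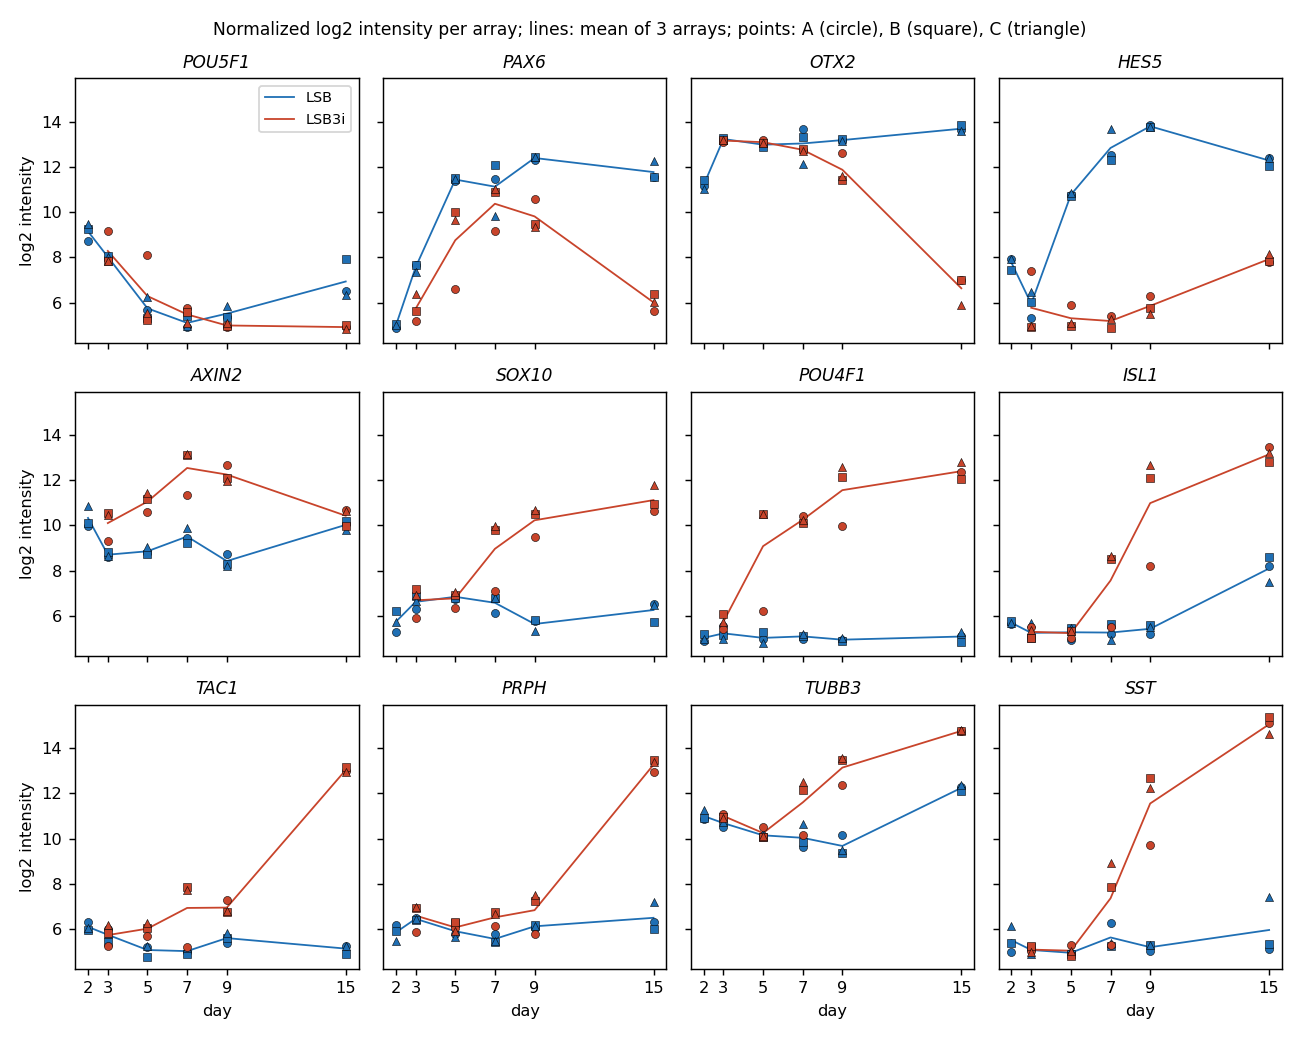
Normalized log2 intensity (y axis) of 12 genes by day (x axis) in LSB and LSB3i; lines join the means of 3 arrays and points are single arrays. At day 15, TAC1 and PRPH are higher in LSB3i and OTX2, PAX6 and HES5 in LSB.

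**Figure D4:**
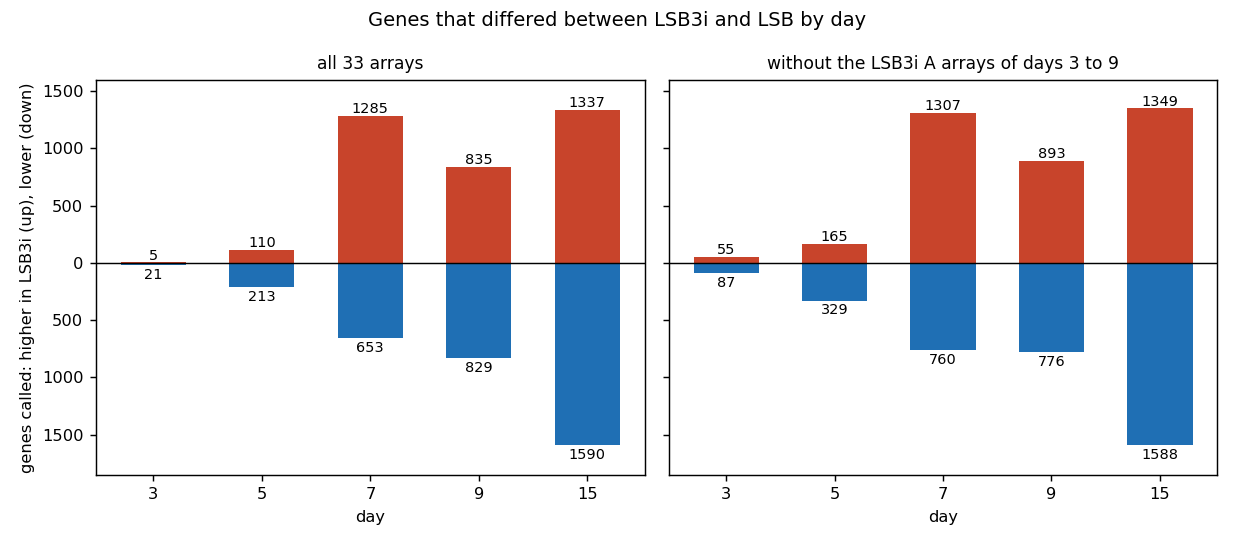
Number of genes higher (up) and lower (down) in LSB3i than in LSB (y axis) by day (x axis), with all 33 arrays and without the LSB3i A arrays of days 3 to 9.

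The next comparison asks how LSB cells themselves changed by day 15. From day 2 to day 15, LHX2 rose at least 139-fold (adjusted p = 1.9e-15), PAX6 at least 32.3-fold and SIX6 at least 34.1-fold. DLK1, a membrane protein of the Notch ligand family, rose by 7.87 ± 0.68, FLRT3 by 6.54 ± 0.44 and LEFTY2 at least 34.2-fold. CUZD1 was at least 106-fold lower and the neuronal pentraxin gene NPTX1 fell (-6.47 ± 0.62). The pluripotency factor genes NANOG (-1.86 ± 0.31) and POU5F1 (-2.22 ± 0.49) fell. TAC1 (adjusted p = 0.0553) and POU4F1 (adjusted p = 0.954) were at background on both days and did not pass.

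Anterior neuroectoderm genes rose (17 of 24, with 17 higher and 0 lower adjusted over the list alone, adjusted p = 5.5e-13), OTX2 among them (adjusted p = 2.5e-07). BMP and TGF-beta targets rose (10 of 11, with 10 higher and 0 lower adjusted over the list alone, adjusted p = 3.4e-05), among them ID1 (3.09 ± 0.59) and the inhibitory SMAD gene SMAD6 (at least 4.59-fold). Pluripotency genes fell (1 higher and 11 lower of 16, with 1 higher and 11 lower adjusted over the list alone, adjusted p = 1.5e-04). The pluripotency list gave adjusted p = 0.146 with an estimated correlation. Notch targets had 7 higher and 1 lower of 11 (7 higher and 1 lower adjusted over the list alone, adjusted p = 0.0246), with HES5 at 4.52 ± 0.44. The Notch list gave adjusted p = 0.184 with an estimated correlation and 0.0622 with only the groups compared. Stress genes were higher (8 of 13, with 8 higher and 0 lower adjusted over the list alone, adjusted p = 0.00114), with TRIB3 at 3.68 ± 0.40. The stress list gave adjusted p = 0.146 with an estimated correlation. Against day 3 the anterior neuroectoderm (12 higher and 1 lower of 24, with 12 higher and 1 lower adjusted over the list alone, adjusted p = 6.2e-06) and BMP and TGF-beta lists (8 higher and 0 lower of 11, with 8 higher and 0 lower adjusted over the list alone, adjusted p = 5.9e-05) rose too. Notch targets (5 higher and 0 lower of 11, with 5 higher and 0 lower adjusted over the list alone, adjusted p = 0.00132) and stress genes (8 higher and 0 lower of 13, with 9 higher and 0 lower adjusted over the list alone, adjusted p = 1.5e-05) rose in the same comparison. FGF/ERK targets (9 higher and 3 lower of 17, with 9 higher and 3 lower adjusted over the list alone, adjusted p = 0.00823) and mesenchyme and smooth muscle genes (7 higher and 0 lower of 12, with 7 higher and 1 lower adjusted over the list alone, adjusted p = 0.00563) also rose against day 3. Pluripotency (2 higher and 9 lower of 16, with 2 higher and 10 lower adjusted over the list alone, adjusted p = 0.0161) and hypoxia and glycolysis genes (2 higher and 9 lower of 17, with 2 higher and 9 lower adjusted over the list alone, adjusted p = 0.0161) fell. With an estimated correlation these 4 lists gave adjusted p = 0.176, 0.141, 0.334 and 0.188, and the mesenchyme list gave 0.0667 with probes on at least 17 arrays. NANOG was at least 2.4-fold higher at day 15 (adjusted p = 3.5e-05).

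From day 2 to day 15 in LSB, 2690 genes changed, 1442 up and 1248 down, and from day 3 to day 15, 2282, of which 1069 went up and 1213 down. Non-overlapping groups numbered 2538 and 2225 (10% by chance). The LSB day 15 arrays were dimmer (mean signals 427 to 513) than those of LSB day 3 (651 to 734). An effect of brightness on these counts was not separated from that of day. From the authors' processed values the counts were 1370 and 1052, and NANOG against day 3 stood at 0.82, short of 2-fold.

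The change in LSB3i cells from day 3 to day 15 was tested in the same way, with no untreated cells beside it. SST rose at least 292-fold (adjusted p = 3.2e-12), SYT4 at least 268-fold, ISL1 at least 77.8-fold and TAC1 at least 71.9-fold. SNAP25, a protein of synaptic vesicle fusion, rose at least 55.2-fold, RTN1 by 7.19 ± 0.38 and SLC17A6 at least 34.9-fold. OTX2 (-6.54 ± 0.30) and POU5F1 (at least 2.7-fold lower) fell, as did ZFP42 (-5.89 ± 0.47), another pluripotency gene. PAX6 was at background on both days (adjusted p = 0.715).

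Pan-neuronal (34 higher and 1 lower of 38, with 34 higher and 1 lower adjusted over the list alone, adjusted p = 9.8e-19) and sensory neuron genes (12 higher and 0 lower of 16, with 12 higher and 0 lower adjusted over the list alone, adjusted p = 8.4e-08) rose. Neural crest genes rose (13 higher and 1 lower of 19, with 13 higher and 1 lower adjusted over the list alone, adjusted p = 1.8e-04), with EDNRB, the endothelin B receptor, at 4.46 ± 0.43. The neural crest list gave adjusted p = 0.128 with an estimated correlation. Mesenchyme and smooth muscle genes rose beside them (9 higher and 2 lower of 12, with 9 higher and 2 lower adjusted over the list alone, adjusted p = 0.00406), with adjusted p = 0.0935 with an estimated correlation and 0.0534 with probes on at least 17 arrays. The medians of the neural crest and mesenchyme lists were 2.88 and 2.70 as fitted, and 2.06 and 1.97 with values at background set to the floor. Cholesterol synthesis genes rose (9 higher and 0 lower of 13, with 9 higher and 0 lower adjusted over the list alone, adjusted p = 6.8e-05). HOX genes rose as well (2 higher and 0 lower of 3, with 2 higher and 0 lower adjusted over the list alone, adjusted p = 0.0194). The HOX list gave adjusted p = 0.107 with no detection filter, 0.885 with probes on at least 17 arrays and 0.0745 with only the groups compared. Pluripotency genes fell (13 of 16, with 0 higher and 13 lower adjusted over the list alone, adjusted p = 1.9e-05), as did cell cycle genes (20 of 29, with 0 higher and 20 lower adjusted over the list alone, adjusted p = 1.0e-06), such as CCNB1 (-2.71 ± 0.30) and KIF11 (-2.39 ± 0.22), and surface ectoderm genes (8 of 11, with 0 higher and 8 lower adjusted over the list alone, adjusted p = 3.7e-04). The anterior neuroectoderm list split into 8 higher and 7 lower of 24 (8 higher and 7 lower adjusted over the list alone, adjusted p = 0.565), with SOX2 at -2.34 ± 0.28 and DACH1 at least 12.9-fold higher. FGF/ERK targets rose (10 higher and 2 lower of 17, with 11 higher and 2 lower adjusted over the list alone, adjusted p = 0.00978), with SPRY4 higher (3.48 ± 0.31) and EGR1 lower (-3.87 ± 0.39). The FGF/ERK list gave adjusted p = 0.128 with an estimated correlation.

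Between day 3 and day 15 of LSB3i 4267 genes changed, 1971 up and 2296 down, and 4131 had non-overlapping groups (10% by chance). The count was 2655 from the authors' processed values, and the sensory neuron list did not pass with probes on at least 17 arrays (adjusted p = 0.162). The median of all genes lay at -0.11. Here too the day 15 arrays were dimmer (448 to 485, against 694 to 713 at day 3), and brightness was not separated from day.

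The last comparison tests whether the change from day 3 to day 15 differed between the treatments, as the LSB3i change minus the LSB change. The rise was greater in LSB3i for SST (adjusted p = 4.9e-08), TAC1 (adjusted p = 4.8e-11), PRPH (adjusted p = 9.0e-11) and SOX10 (adjusted p = 8.7e-06). OTX2 differed by -7.00 ± 0.42, and LHX2 (adjusted p = 3.3e-11) and LEFTY2 (adjusted p = 4.7e-14) differed in the same direction. POSTN, a matrix protein (adjusted p = 8.7e-14), and PHACTR3 (adjusted p = 1.6e-10) rose more in LSB3i and were at background in LSB at both days. FOS had the lower change in LSB3i (adjusted p = 6.2e-05). No size is given where a gene was at background on all arrays of a group.

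Pan-neuronal genes rose more in LSB3i (33 of 38, with 34 higher and 0 lower adjusted over the list alone, adjusted p = 4.9e-26), as did sensory neuron genes (12 higher and 1 lower of 16, with 12 higher and 1 lower adjusted over the list alone, adjusted p = 4.5e-10) and cholesterol synthesis genes (8 of 13, with 9 higher and 0 lower adjusted over the list alone, adjusted p = 6.3e-06). Cell cycle genes (21 of 29, with 0 higher and 21 lower adjusted over the list alone, adjusted p = 3.9e-08), surface ectoderm genes (10 of 11, with 0 higher and 10 lower adjusted over the list alone, adjusted p = 9.9e-06) and anterior neuroectoderm genes (13 of 24 lower, 1 higher, with 2 higher and 13 lower adjusted over the list alone, adjusted p = 2.1e-04) had the lower change in LSB3i. Neural crest genes had 10 higher and 1 lower of 19 (11 higher and 1 lower adjusted over the list alone, adjusted p = 2.1e-04). The neural crest list gave adjusted p = 0.131 with an estimated correlation.

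In all, 2640 genes differed in their change, 1301 higher and 1339 lower in LSB3i. The count was 1742 from the authors' processed values, and the sensory neuron list did not pass with probes on at least 17 arrays (adjusted p = 0.487).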

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

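The tests of the 3 patterns below were chosen only after the result was seen, while the comparison of changes and the other splits of the arrays were planned. The LSB3i and LSB changes from day 3 to day 15 differed in 2640 genes by the test of the difference itself, which is why they are listed here. Of 100 drawn splits that reassign treatments within each day, 1 gave as many, the real one, and the highest other split gave 2635. It is among 6 that keep the day 15 arrays together, as labelled or swapped whole (2424 to 2635 genes), and the other 93 gave at most 5. The count thus rests on the 6 day 15 arrays, whose 10 splits are too few for a share under 0.05, so the share of 1 in 100 is not taken to exclude chance.

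Gene lists whose changes differed are given by the median of fitted differences, and in brackets the median with values at background set to the floor. Higher in LSB3i were sensory neuron 4.63 (3.21), pan-neuronal 4.34 (3.00), HOX 4.06 (2.93), central neuron 2.75 (1.06), neural crest 2.28 (1.21), autonomic neuron 2.14 (0.37) and cholesterol synthesis 1.16 (1.16). Lower were surface ectoderm -2.56 (-1.40), melanocyte -2.08 (-1.87), anterior neuroectoderm -1.45 (-1.07), cell cycle -1.35 (-1.32) and pluripotency -1.22 (-0.83). The call was lost for pluripotency (adjusted p = 0.0539 with an estimated correlation), neural crest (adjusted p = 0.131 with an estimated correlation), melanocyte (adjusted p = 0.0566 with an estimated correlation) and central neuron genes (adjusted p = 0.0539 with an estimated correlation). With probes on at least 17 arrays the sensory neuron (0.487), HOX (0.527), melanocyte (0.0557), autonomic (0.166) and central neuron lists (0.436) lost it too, all adjusted p. With no detection filter the last 4 gave adjusted p = 0.155, 0.104, 0.286 and 0.103, and medians of 0.02, 0.01, -0.09 and 0.11. At a detection threshold of 0.05 the melanocyte and autonomic lists gave adjusted p = 0.0783 and 0.234, and the central neuron list gave 0.0788 without the LSB3i A arrays and 0.11 without the 6 arrays that stand apart. FOS was called in opposite directions at day 3 (1.94 ± 0.38) and day 15 (adjusted p = 0.0124). The fitted difference of -3.11 ± 0.53 (adjusted p = 6.2e-05) is no bound, since FOS was at background at LSB3i day 15. Its day 15 call was lost without LSB day 15 array A, LSB day 15 array C or LSB3i day 15 array C (adjusted p = 0.0746, 0.14 and 0.0645), and its day 3 call without LSB day 3 array B, LSB3i day 3 array B or LSB3i day 3 array C (adjusted p = 0.176, 0.106 and 0.0645).

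For the other 8 comparisons, 3 arrays against 3 make 10 splits, too few for a share under 0.05, and 1 of 10, the real one, gave as many genes each time. Real counts and the highest of the other splits were 26 and 2 at day 3, 323 and 2 at day 5, 1938 and 354 at day 7, 1664 and 2 at day 9, and 2927 and 17 at day 15. They were 2690 and 116 for LSB day 15 against day 2, 2282 and 0 against day 3, and 4267 and 7 for LSB3i day 15 against day 3.

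The LSB3i arrays lettered A of days 5, 7 and 9 lie nearest the day before their label. On an axis from the B and C arrays of the day before (near 0) to those of the labelled day (near 1) they lie at 0.148, 0.164 and 0.187, against 0.068 to 0.197 for B and C of the day before. A mixture with a large share of cells of the labelled day is argued against by 0 of 3 A arrays lying between the days. A small share of such cells could not be seen, given the spread of B and C of the day before. The same 3 places serve the test of the labels, so the 2 tests are not separate evidence. Labels shifted by 1 sampling day may explain these 3 arrays, since the highest place, 0.187, lies within the range of the day before. The array labelled day 15 A did not share the shift. Its mean correlation was 0.958 with B and C of day 15 and 0.864 with those of day 9. A shift of labels would thus have to leave out day 15. A culture 2 days behind through day 15 stays open, since the array labelled day 15 A, at 0.824 on the axis from day 9, lies between B and C (0.808 and 0.899), which decides neither way, and a culture that caught up after day 9 was not tested.

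At day 7 more genes were higher than lower in LSB3i. The split depends on the scaling: with median scaling 31.5% of calls were higher, but that scaling moved the median of all genes from 0.086 to -0.132, a shift of all genes that can turn the split alone, so it does not say which scaling is right. A rise within LSB3i between days 5 and 9 also stays open: 32.9% of the genes higher at day 7 were called higher at day 5 or day 9, against 61.6% of the lower ones. The LSB day 7 group stood apart, with a lowest pair correlation of 0.841 and a residual SD of 0.813, against at most 0.457 in the other groups, and neither explanation is decided.

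LEFTY2, NANOG and POU5F1 were higher at LSB day 15 than at LSB day 9, although POU5F1 was detected on 1 of 3 arrays at day 15 (mean 6.94, near background). Cells unchanged since LSB day 2 are argued against for LEFTY2, which was at least 34.2-fold higher at LSB day 15 than at LSB day 2. The day 2 level was measured under an inhibitor of the nodal receptors. It therefore does not argue against remaining day 2 cells in which LEFTY2 rose later, which was not tested. Dim day 15 arrays are argued against by all 3 genes being lower in the LSB3i day 15 arrays, which were as dim. For NANOG and POU5F1 cells like those of LSB day 2 remain open. Of the 3 other pluripotency genes detected at LSB day 2 and not at day 9, 1 (GAL) was higher at day 15. PRDM14 and POLR3G, at background, were not. SMAD signalling returning by day 15 may contribute: 70% of the other tested BMP and TGF-beta targets, 7 of 10, were higher at day 15 than at day 9, ID1, ID2, ID3 and SMAD6 among them, and CCN2 was lower. PMEPA1, also among the 7, was detected on 1 of 3 arrays at day 15 (mean 6.53, near background). The share of all genes called higher between these days is not given here, so the 70% has no baseline. The labels do not say until which day the receptor inhibitors were given.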

How the results depend on the processing

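Leaving out the LSB3i A arrays of days 3 to 9, or 6 arrays that stand apart, was chosen only after the result was seen, and the other changes of setting were planned. Without the A arrays 142 genes differed at day 3 and 494 at day 5, and without the 6 arrays 206 and 611. Array weights gave 224 and 639, and probes on at least 17 arrays 16 at day 3. With the authors' processed values the counts were 170 (day 5), 798 (day 7), 786 (day 9), 1662 (day 15), 1370 and 1052 (LSB day 15 against days 2 and 3), 2655 (LSB3i) and 1742 (difference of changes). Background correction with an offset of 50 and no detection p-values gave 1182 at day 7, 1081 at day 9 and 1493 for LSB day 15 against day 3, and only the groups compared gave 714 at day 7. With no fold minimum the counts were 501, 3391, 2865 and 4581 at days 5, 7, 9 and 15, and 4319 and 3782 in LSB against days 2 and 3. A 1.5-fold minimum gave 490, 3117, 2638 and, for LSB against day 3, 3483. Leaving out 1 array gave 11 (without LSB3i day 3 C) to 90 (without LSB3i day 3 A), 200 (without LSB day 5 A) to 368, 1556 to 2430, 1416 to 1628 and 2853 to 2962 at days 3 to 15, 2597 to 2747 and 2069 to 2308 in LSB, 4136 to 4272 in LSB3i, and 2370 to 2642 for the difference. The letter as a block gave 28, 322, 1948, 1660, 2924, 2692, 2291, 4260 and 2638. The cause of these shifts was not tested. Of 749 called values among the 925 that the naming rule allows, 179 lost the call under at least 1 planned change of setting and 114 when 1 array was left out. Direction turned in 12. With probes on at least 17 arrays TFAP2A stood at -0.023, -0.67 and -0.51 at days 5, 9 and 15, at -0.27, -1.39 and -1.60 in LSB against days 2 and 3 and in LSB3i, and at -0.21 for the difference. With median scaling at day 7 CLDN6 stood at -0.050, GAS7 at -0.10 and HOXB2 at -1.13, and with the mean of all probes IL17RD (LSB against day 3) at 0.79 and L1CAM (LSB3i) at 1.06. The HOX list of LSB3i day 15 against day 3 turned to -0.28 with probes on at least 17 arrays. Of 77 list results past the threshold, 30 were lost with an estimated correlation, 23 under at least 1 such change with camera and 2 without the A arrays, and 16 others were gained there. A BeadChip block was not run.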

Other observations

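All tests behind this part were chosen only after the result was seen, and the genes named here were chosen after their values were seen. CHCHD2 stood at 7.14 ± 0.40 (log2 intensity ± SD, n = 3) at LSB day 15, 3.32 below every other array, while the next such gap in that group was 0.785 and the other group means ranged from 10.98 to 12.81. The value comes from 1 probe. LEFTY2 stood at 11.87 ± 0.36 at LSB day 15 and was detected on no array of any other group. At LSB3i day 15, 1133 genes lay above and 825 below all other arrays.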
